A study of Caenorhabditis elegans with 3 samples.

How the data were processed

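Total RNA from whole N2 larvae at the L1 stage was extracted with Trizol after bead homogenization, purified on columns and treated with DNase, and 200 ng per sample was amplified, labelled with biotin and hybridized to Affymetrix C. elegans arrays, per the labels' protocols. The series holds 3 arrays: 1 control, 1 bio-electrospray and 1 heat shock (30 °C for 24 h). The labels describe a supply of up to 30 kV for the spraying, and the voltage applied was not used here. Nothing in the labels gives the age of each group at collection beyond the L1 stage.

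The deposited values are GCRMA levels, with the method named in the submitters' processing notes and its version and options not given in the sources used here. As usually run, GCRMA corrects background from probe sequence, normalizes probes between arrays by quantiles and summarises each probe set. The scale of the deposited levels was taken as log2 because GCRMA writes log2 values and the values ran from 1.81 to 13.96. A pair of properties of such levels bears on the differences. Dim probe sets lie on a floor of about the same value, so a fold against a gene near the floor depends on the background model. Also, 6303 of 22625 probe sets (27.9%) had exactly equal values on the bio-electrospray and control arrays, 3167 (14.0%) on the heat shock and control arrays and 2215 (9.79%) on all 3, which is why many list medians are exactly 0. Scanner files were not used here.

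Probe sets were named through the platform annotation, with 20766 probe sets of 1 gene symbol, 887 of several and 972 of none, 77 of the last being Affymetrix control probe sets. The genes of 20701 of the single-symbol probe sets were found in the RefSeq gene table. No gene was named from a probe set with several symbols, except where it is given as the set of its genes. The single-symbol probe sets covered 17118 genes, of which 2981 had more than 1 probe set, and the brightest over the 3 arrays stood for the gene. Names of 6711 probe sets mark them as possibly shared between transcripts, which matters for families of near-identical genes such as the msp, histone and ilys genes.

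With 1 array per group no statistical test was run. For each of the 3 comparisons (bio-electrospray against control, heat shock against control, heat shock against bio-electrospray) the log2 levels were subtracted, and probe sets at least 2-fold apart (log2 difference of 1) were counted among those above the array median (percentile 50) on at least 1 of the arrays compared. A set of 43 gene lists covering heat shock proteins, other stress responses, defence, metabolism, the cell cycle, the cuticle and tissues was fixed before the data were examined; 32 member names were not found on the array. For each list with at least 3 members above the filter, the median difference was given with a 95% order-statistic interval over its genes, which describes the spread between genes and not between cultures, and with its percentile among 10000 random lists of the same size matched on mean level in 10 bins. Genes were named by a rule also fixed beforehand: the 10 with the largest positive and the 10 with the largest negative difference from control, the members of both heat shock protein and chaperone lists, and up to 4 members with the largest absolute difference in every other list. Some names lie outside this rule: those said to be so, those of an overlap of 2-fold probe sets, and further members of some described lists.

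The overlap of the bio-electrospray and heat shock differences was set beside 100 simulations of 3 arrays that differ by noise only and beside the overlap of independent lists. Agreement between different probe sets of 1 gene, the hybridization spike-in probe sets and the level of 5′ against 3′ control probe sets served as views of technical spread; they leave out differences between cultures.

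The counting step was tested on data simulated for heat shock against control and the list step on data simulated for bio-electrospray against control. All 100 probe sets moved by 1.5 and all 100 moved by 3 (log2) were counted as 2-fold apart, as were 18 of 11310 unmoved ones (0.159%), and 92 of 100 unchanged random lists lay inside the middle 95% of matched lists. The moved probe sets were picked among brighter ones, so recovery near the floor was not tested. The noise was drawn from the bio-electrospray minus control differences, so the share of unmoved ones is no independent error rate. Alternatives covered quantile normalization, median centring and loess centring (span 0.3), no level filter, a filter at the 75th percentile or in both arrays, an offset of 16 on the linear scale, probe sets not shared between transcripts, fold thresholds of 1.5 and 3, the mean over probe sets, and probe sets of several genes. The closing section gives their effect. The number of columns that belong to no sample was 0. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.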

Results

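RNA was measured in whole larvae of the wild-type Bristol strain N2 of the nematode Caenorhabditis elegans, given by the labels as first larval stage (L1). There were 3 groups with 1 Affymetrix array each: untreated larvae, larvae passed through a needle under an applied voltage (bio-electrospray, a jet method for placing living material in droplets), and larvae held at 30 °C for 24 h. The parents had been kept at 20 °C on a lawn of Escherichia coli OP50. The heat-shocked group served as a positive control for a stress response, and the question was how far the transcripts of the electrosprayed larvae departed from those of untreated ones. Each array reported 22625 probe sets as log2 levels, with medians of 3.147 on the control array, 3.157 on the bio-electrospray array and 3.189 on the heat shock array. The number of arrays limits the precision. With no replicate in any group, the differences below have no replicate check, and no p-value is given. A difference was counted by size, at least 2-fold, among probe sets brighter than the array median on at least 1 of the arrays compared.

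Across all probe sets the levels of the bio-electrospray and control arrays had a Pearson r of 0.998, against 0.948 for heat shock and control; these are correlations across probe sets, which are not independent replicates. The 18 hybridization spike-in probe sets, which measure transcripts added during the assay and not worm RNA, gave a view of technical offsets. Their median difference from control was −0.19 on the bio-electrospray array (range −0.48 to 0.01) and −0.53 on the heat shock array (range −1.07 to −0.15). Of the genes with a second probe set above the filter, 255 had a first probe set at least 2-fold apart between heat shock and control. In 246 of them the second probe set differed in the same direction, and in 147 it was also at least 2-fold apart.

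The electrosprayed larvae differed from untreated ones in few transcripts. The acyl-CoA dehydrogenase gene acdh-2 was 8.85-fold higher, at a log2 level of 6.38 against 3.24, and its second probe set was higher by 2.49. Its control level lay near the array median, and with 16 added to the linear levels acdh-2 was 3.91-fold higher. The related gene acdh-1, whose product acts in the breakdown of propionate, was 3.11-fold higher, at 10.83 against 9.20. The C-type lectin gene clec-47 was 4.78-fold higher and ugt-26, which encodes a UDP-glucuronosyltransferase of the kind that attaches sugars to foreign compounds, was 3.65-fold higher. In the other direction the C-type lectin gene clec-258 was lower by −1.98, the stearoyl-CoA desaturase gene fat-7 by −1.34 and the arginine kinase gene argk-1 by −1.31 on the log2 scale. Of 11454 probe sets compared, 27 were at least 2-fold higher and 5 at least 2-fold lower after bio-electrospray, 0.279% in all. Counted once per gene, 22 of 8614 genes were higher and 4 lower. The middle 95% of all differences lay between −0.39 and 0.31.

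The other genes among the 10 highest after bio-electrospray were Y58A7A.5 (log2 difference 2.60), Y58A7A.3 (2.20), C49G7.10 (1.48), K11H12.4 (1.43), the sugar transporter gene swt-6 (1.39) and rcd-1 (1.37). Only 4 genes were at least 2-fold lower, the last of them igcm-1 (−1.05), which encodes an immunoglobulin-type cell adhesion molecule. Just short of 2-fold, the list of the 10 lowest went on with the amine oxidase gene amx-3 (−0.998), dod-24 (−0.91), C30E1.9 (−0.88), the major sperm protein genes msp-77 (−0.90) and msp-36 (−0.86), and nas-37 (−0.87), an astacin protease gene used in moulting. Further probe sets past 2-fold, named here after their values were seen, measured the transporter genes pgp-6 and pgp-7 together (2.13) and pgp-5 (1.09), the claudin-like gene clc-19 (1.303), dhs-25 (1.06), irg-1 (1.02) and hphd-1 (1.02), the last an enzyme gene of propionate breakdown. Of the 26 genes at least 2-fold apart, 11 stayed so when 16 was added to the linear levels, which shrinks differences between dim probe sets.

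**Figure D1:**
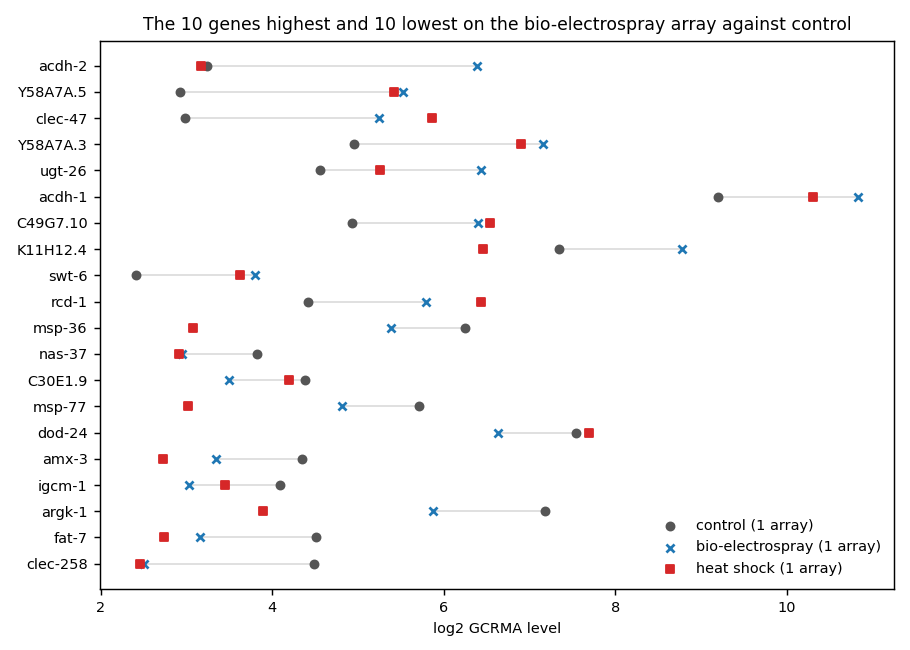
Log2 levels on the 3 arrays of the 10 genes with the largest positive and the 10 with the largest negative difference between bio-electrospray and control. Each symbol is 1 array, and a grey line joins control to bio-electrospray. The gene acdh-2 stands at 6.38 on the bio-electrospray array and at 3.24 and 3.17 on the control and heat shock arrays, while clec-47 is high on both treated arrays.

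None of the heat shock protein or chaperone genes was 2-fold apart after bio-electrospray. The small heat shock protein hsp-16.2, the classic heat-inducible chaperone of the worm, stood at 3.54 against 3.03 on the control array, a difference of 0.51, and sip-1 differed by 0.37. Differences were 0.10 for hsp-25, −0.12 for hsp-17 and −0.26 for hsp-43, and the median over the 7 small heat shock genes above the filter was 0 (95% order-statistic interval over genes −0.26 to 0.51). Among 16 inducible and cytosolic HSP70, HSP90 and HSP110 chaperone genes the median was also 0 (−0.01 to 0.15), with hsp-70 at 0.33, dnj-13 and chn-1 at 0.21 each, cdc-37 at 0.15, hsp-90 at −0.07 and hsp-1 at −0.06. The shared probe sets of hsp-16.1 with hsp-16.11 and of hsp-16.48 with hsp-16.49 differed by 0.23 and 0.11, and those of F44E5.4 with F44E5.5 by 0.24 and 0.35. The small heat shock list stayed inside the range of random lists matched on level in 9 of 10 alternative settings. With probe sets of several genes counted it lay above that range, with a median of 0.11 (percentile 99.92).

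Of the 42 gene lists with enough members, 4 had a median above and 6 a median below the middle 95% of 10000 random lists matched on level, where 2.1 outside would be found by chance for independent lists; on simulated data 92 of 100 unchanged lists lay inside. These percentiles are a description of these arrays. The sperm list was lowest, with a median of −0.48 (−0.58 to −0.25; percentile 0) over 25 genes, none of them 2-fold apart. Its members msp-65 and msp-78 differed by −0.75 and −0.69. Most of these genes are read by probe sets shared within the family, and over the 5 sperm list genes left without such probe sets the median was 0 (bio-electrospray against control). Moulting genes had a median of −0.13 (−0.22 to −0.06; percentile 0), with mlt-9 at −0.67 and mlt-11 at −0.43. The median of the DNA damage and repair genes was −0.07 (percentile 0.38; cku-80 at −0.39), that of DNA replication and cell cycle genes −0.05 (0.46; bub-1 at −0.33), that of voltage-gated and potassium leak channel genes −0.05 (0.22; twk-17 at −0.55) and that of muscle genes −0.04 (0.63; unc-95 at −0.38). No member of these lists was 2-fold apart. The call below the range held in all 10 alternative settings for moulting, in 8 each for sperm, DNA damage, cell cycle and muscle and in 7 for the channels, whose median was 0 without shared probe sets (bio-electrospray against control).

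Above the random range lay 4 lists with small medians. The UDP-glucuronosyltransferase genes had a median of 0.03 (percentile 99.98), with 2 of 42 members at least 2-fold higher, ugt-26 (1.87) and ugt-29 (1.08). Intestinal genes had a median of 0.07 (99.95), among them the cathepsin B-like proteases cpr-4 (0.37) and cpr-1 (0.25). Lysozyme and other intestinal defence genes had a median of 0.03 (99.8), with irg-1 (1.02) the 1 of 30 at least 2-fold higher and lys-4 at 0.85. The 105 cuticle collagen genes had a median of 0.02 (0.01 to 0.05; percentile 100), none of them 2-fold apart. Equal values narrowed the random range to 0 to 0 for the collagens and to −0.003 to 0 for the UDP-glucuronosyltransferases, so any positive median lay above it. The call held in all 10 alternatives for these 2 lists. It held in 9 for the intestine and in 8 for the lysozymes, whose medians fell to 0.024 and 0.0072 without shared probe sets (bio-electrospray against control). Among 24 genes of fat metabolism, acdh-1 and acdh-2 were 2-fold higher and fat-7 2-fold lower around a median of 0, and among 43 C-type lectin genes clec-47 was higher and clec-258 lower. In every other list no member was 2-fold apart, and the medians lay between −0.01 (CCT chaperonin and prefoldin) and 0.03 (pals genes).

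**Figure D2:**
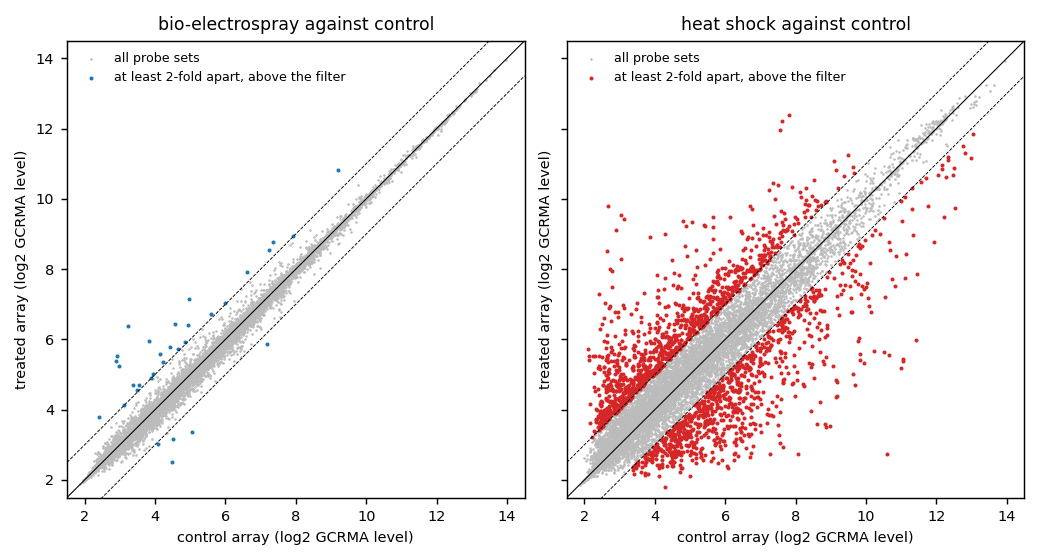
Log2 level of every probe set on the control array (horizontal) and on a treated array (vertical), bio-electrospray on the left and heat shock on the right. The solid line marks equal levels and the dashed lines 2-fold; coloured points are the probe sets counted as 2-fold apart, 0.279% of those compared on the left and 16.45% on the right.

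Heat-shocked larvae differed from untreated ones in a large part of the transcriptome. The small heat shock protein genes hsp-16.2 and hsp-16.41 were 91.9-fold and 73.6-fold higher, at log2 levels of 9.55 against 3.03 and 9.11 against 2.91, and hsp-70 was higher by 3.70. The control levels of these hsp-16 genes lay below the array median, where a fold depends on the background model. The pals genes are a family known for induction by intracellular pathogens. Of 23 with their own probe set 18 passed the filter, and 15 of these were at least 2-fold higher, with pals-6 up by 5.28. Only 5 passed it for bio-electrospray against control, so most of the 18 entered through their level on the heat shock array. On the lower side stood cuticle collagen genes such as col-156 (−5.08) and col-180 (−4.86), major sperm protein genes such as msp-36 (−3.16) and germline genes such as gld-1 (−2.34). Of 11969 probe sets compared, 1042 were at least 2-fold higher and 927 at least 2-fold lower, 16.45% in all. Counted once per gene, 803 of 9013 genes were higher and 742 lower (17.1%). The middle 95% of differences ran from −1.97 to 1.79. With the offset of 16, 803 of the 1545 genes apart stayed 2-fold apart in the same direction.

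The gene with the largest positive difference was ddn-1 (7.14, 141-fold), at 9.80 against 2.67, a control level below the array median. It was followed, beyond the hsp-16 genes, by the C-type lectin genes clec-60 (6.33), clec-17 (5.18) and clec-174 (5.04), by eol-1 (5.88), pals-6, F15D4.5 (5.27) and the ribonuclease H gene rnh-1.3 (4.71). The largest negative difference was that of lep-5 (−7.84), a long non-coding RNA of the larval timing pathway, which stood at 10.59 on the control array and 2.75 on the heat shock array. The invertebrate-type lysozyme gene ilys-5 was lower by −5.67, with further probe sets at −5.60 and −5.82. The other genes among the 10 lowest were nspb-10 (−5.35), abu-15 (−4.96), the RNA-binding protein gene rbm-3.1 (−4.79), K01D12.9 (−4.77), pqn-54 (−4.69) and abu-6 (−4.62), beside col-156 and col-180.

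Small heat shock protein genes had a median difference of 0.68 (0 to 6.20; percentile 99.7), with 5 of 11 at least 2-fold higher and none lower. Besides hsp-16.2 and hsp-16.41 these were hsp-43 (1.40), hsp-12.3 (1.27) and hsp-17 (1.19). Below 2-fold lay hsp-25 (0.68), hsp-16.21 (0.51), sip-1 (0.40), hsp-12.6 (0.31), hsp-12.1 (0) and hsp-12.2 (−0.44). The shared probe sets of hsp-16.1 with hsp-16.11, and of hsp-16.48 with hsp-16.49, were higher by 3.44 and 3.08. The HSP70, HSP90 and HSP110 list had a median of 0.02 (percentile 71.6), with hsp-70 alone of 16 members at least 2-fold higher; the 2 probe sets shared by the HSP70-type genes F44E5.4 and F44E5.5, which are not counted in it, were higher by 2.59 and 3.03. The constitutive chaperones hsp-1 (−0.20), hsp-90 (0.18) and hsp-110 (0.04) lay close to the control level, hsf-1, the heat shock transcription factor, was at 0.55, chn-1 at 0.51, unc-23 at 0.50, bag-1 at −0.30 and the myosin chaperone unc-45 at −0.84. Within the ER unfolded protein response, xbp-1 (1.81) and atf-6 (1.03) were higher and ckb-2 (−1.71) lower among 20 genes with a median of −0.02, while the ER chaperone hsp-4 was at −0.62. None of 10 mitochondrial unfolded protein response genes was 2-fold apart (median −0.35, percentile 3.75), with hsp-6 at −0.54 and lonp-1 at −0.80.

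**Figure D3:**
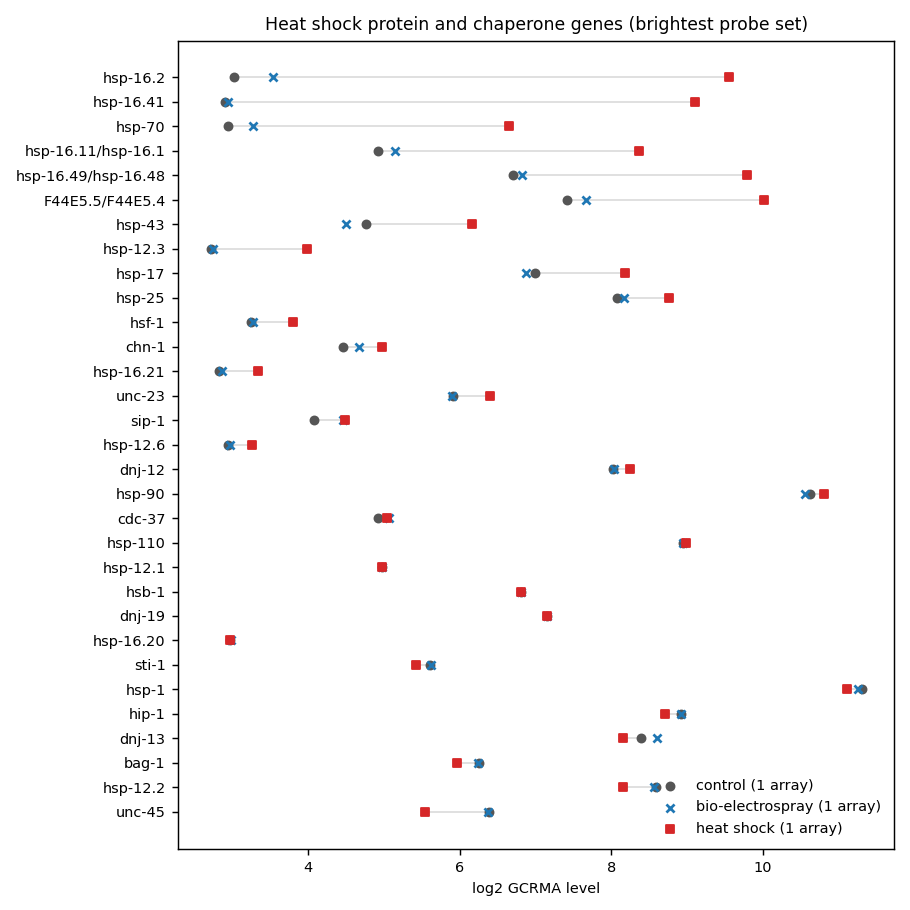
Log2 levels of heat shock protein and chaperone genes on the 3 arrays, 1 symbol per array, ordered by the difference between heat shock and control. Gene pairs joined by a slash share a probe set. The genes hsp-16.2, hsp-16.41 and hsp-70 stand far to the right on the heat shock array (hsp-16.2 at 9.55 against 3.03), while their bio-electrospray symbols lie near the control ones.

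The pals genes as a group had a median of 2.43 (1.08 to 3.02; percentile 100). After pals-6 came pals-27 (3.92), pals-29 (3.81) and pals-33 (3.40), pals-5 was higher by 2.53, and the paired regulators pals-22 and pals-25 stood at 1.08 and 0.70. Most of these genes lay near the floor of the control array, and over those above the median on both arrays the median was 1.06. Among 16 skr and cul genes, components of cullin-type ubiquitin ligases, 6 were at least 2-fold higher and 2 lower around a median of 0.50 (−0.16 to 1.44; percentile 99.7). The higher members included skr-5 (2.02), skr-4 (1.91) and cul-6 (1.88), and skr-2 (−1.26) was lower. The median of this list was 0 without probe sets shared between transcripts (heat shock against control) and −0.023 without the level filter. None of 31 proteasome genes was 2-fold apart (median −0.21, percentile 4.00; pbs-7 at −0.65).

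Genes of the cuticle, the germline and the cell cycle were lower on the heat shock array, where the median of the spike-in probe sets was lower too (−0.53). Of 105 cuticle collagen genes 48 were at least 2-fold lower and 6 higher, with a median of −0.88 (−1.14 to −0.63; percentile 0). The lower ones included col-109 (−3.83) and col-77 (−3.75), whereas col-149 was higher by 2.89. Of 24 moulting genes 6 were 2-fold lower and none higher (median −0.77, percentile 0), among them mlt-8 (−2.28), mlt-10 (−2.24) and bli-5 (−1.90). In the germline list 13 of 24 genes were 2-fold lower and none higher (median −1.199, −1.85 to −0.72; percentile 0), with the Argonaute gene wago-1 at −3.32, cpg-2 at −2.19, csr-1 at −2.09 and the P granule gene pgl-3 at −1.87. The sperm list had 16 of 25 genes lower (median −1.64, −2.26 to −0.85; percentile 0), such as msp-78 (−2.99) and msp-53 (−2.75), and its median was −0.044 over the 5 genes left without shared probe sets (heat shock against control) and −0.038 without the level filter. Among 30 DNA replication and cell cycle genes 10 were lower and 1 higher (median −0.78, percentile 0), including cyb-1 (−1.95), mcm-7 (−1.89) and plk-1 (−1.80), and the 1 higher was the cell cycle inhibitor cki-1 (1.06). A single yolk gene passed the filter, too few for a summary.

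Synaptic and neuropeptide genes stood higher as groups. In the synaptic list 4 of 22 genes were at least 2-fold higher and none lower (median 0.69, 0.44 to 0.95; percentile 100), with the neuropeptide-processing genes egl-21 (1.85) and egl-3 (1.33) and the glutamate decarboxylase gene unc-25 (1.5). Of 22 FMRFamide-like neuropeptide genes 7 were higher and none lower (median 0.70, 0.38 to 1.23; percentile 100), led by flp-15 (1.89), flp-4 (1.38) and flp-3 (1.35). Voltage-gated and potassium leak channel genes had 4 of 31 members higher (median 0.27, percentile 98.9; twk-49 at 1.32), and none of 10 mechanosensation genes was 2-fold apart (median 0.45, percentile 97.6; mec-7 at 0.90). Histone genes had a median of 0.59 (0.39 to 0.91; percentile 100), with 5 of 29 higher and 2 lower. Among them the linker histone genes went both ways, hil-7 at 3.83 and hil-5 at −2.80, while the core histone genes his-42 and his-41 were higher by 1.46 and 1.37. Dosage compensation and Polycomb-type genes had a median of 0.27 (percentile 97.8), with dpy-27 (1.41) higher and mes-4 (−1.28) lower out of 18. The call above the random range held in 9 of 10 alternative settings for the channel list, 6 for mechanosensation (median 0 at the lowest), 6 for dosage compensation and Polycomb-type genes (percentile down to 92.8) and all 10 for the synaptic, neuropeptide and histone lists.

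**Figure D4:**
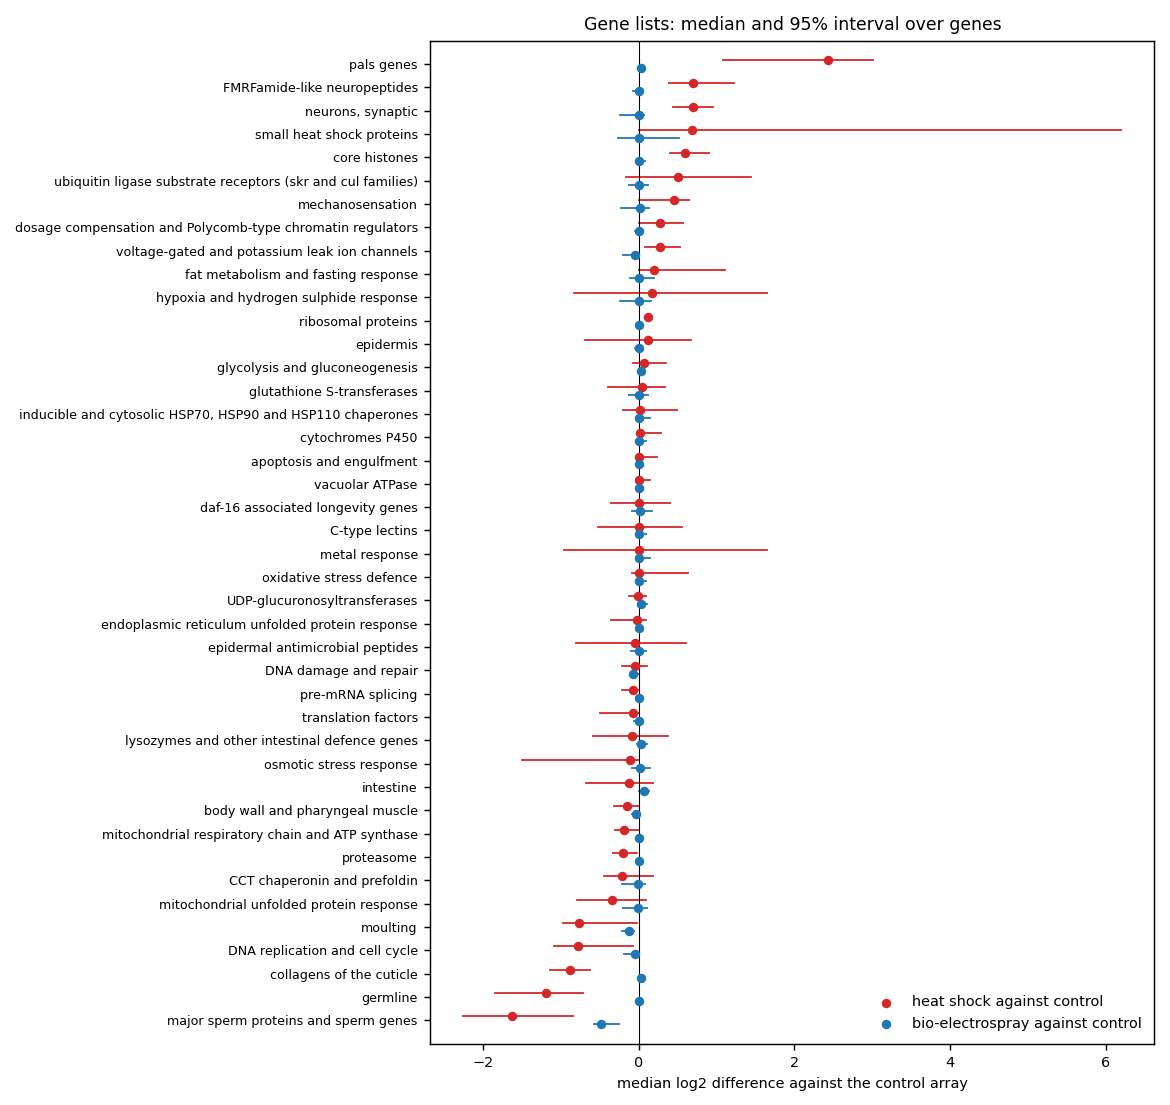
Median log2 difference from the control array for each of 42 gene lists (points) with its 95% order-statistic interval over genes (lines), for heat shock and bio-electrospray; the intervals do not cover differences between cultures, and the pals list had too few members for one after bio-electrospray. The pals list lies at 2.43 and the sperm list at −1.64 after heat shock, while all bio-electrospray medians except that of the sperm list (−0.48) lie between −0.13 and 0.07.

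In fat metabolism 8 of 25 genes were at least 2-fold higher and 1 lower (median 0.19, percentile 97.9), and the list stayed above the random range in 6 of 10 alternatives (percentile down to 91.6). The fatty acid desaturase genes fat-2 (1.98), fat-4 (1.73), fat-3 (1.27) and fat-6 (1.16), the lipase gene lipl-1 (2.69) and the acetyl-CoA carboxylase gene pod-2 (1.26) were higher, and fat-7 (−1.76) was the 1 lower. Cytosolic ribosomal protein genes were slightly higher together, with a median of 0.12 (0.08 to 0.16; percentile 99.8) and none of 63 at 2-fold. Respiratory chain and ATP synthase genes had a median of −0.19 (percentile 3.30) with 1 of 34 lower, ucr-2.3 (−1.51). No glycolysis and gluconeogenesis gene of 21 (median 0.07; pck-2 at 0.94), no vacuolar ATPase gene of 19 (median 0.00; vha-7 at 0.89) and no CCT chaperonin or prefoldin gene of 14 (median −0.21; cct-8 at −0.54) was 2-fold apart. Translation factors had 4 of 36 members lower and 1 higher (median −0.08), among them iff-1 (−3.84), the germline form of eIF5A, and ife-5 (1.29). Splicing genes had 2 of 40 lower, snr-2 (−1.04) and rsp-4 (−1.02), around a median of −0.07.

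Defence and detoxification genes went both ways. Of 46 C-type lectin genes 10 were higher and 9 lower (median 0), with clec-4 at −3.32 opposite clec-60. Lysozyme and intestinal defence genes had 4 of 32 higher and 7 lower (median −0.09), including spp-18 (3.32), irg-5 (3.05) and spp-4 (−2.53). Epidermal antimicrobial peptide genes had 3 of 17 each way (median −0.04), with cnc-4 at 2.73 and nlp-25 at −2.87. Glutathione S-transferase genes had 2 of 25 higher and 5 lower (median 0.05), with gst-24 at 3.80, gst-13 at −2.13 and gst-4 at −1.60. UDP-glucuronosyltransferase genes had 3 of 44 higher and 7 lower (median −0.01; ugt-39 at 3.12, ugt-47 at −2.56), and cytochrome P450 genes 4 of 29 higher and none lower (median 0.02; cyp-37B1 at 1.69). Superoxide dismutase genes sod-4 (2.1), sod-3 (1.85) and sod-5 (1.19) were the 3 higher members among 19 oxidative stress genes (median 0), where prdx-6 (−1.06) was lower.

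Among the remaining stress lists, the metallothionein gene mtl-1 (3.61) and the ferritin gene ftn-1 (1.64) were higher and cdr-2 (−1.89) lower in a metal response list of 11 (median 0). The osmotic stress list of 10 (median −0.11) held the glycerol-3-phosphate dehydrogenase gene gpdh-1 (−1.93), aqp-8 (−1.50) and hmit-1.3 (−1.23) on the lower side and the trehalose synthase gene tps-1 (1.57) on the higher. In the hypoxia list of 9 (median 0.17) F22B5.4 (2.91) and ftn-1 were higher, and in the list of 21 genes associated with the FOXO factor daf-16 (median 0) mtl-1, sod-3 and dod-3 (1.06) were higher and dod-17 (−2.02) lower. The cell death trigger egl-1 (1.44) was higher in the DNA damage list of 22 (median −0.05), which had phg-1 (−2.18) and exo-1 (−1.03) lower, and together with cps-6 (1.5) in the apoptosis list of 15 (median 0.00). Of the tissue lists, muscle had 5 of 32 genes lower and none higher (median −0.15; unc-22 at −2.07, myo-1 at −1.29), intestine 6 of 24 lower and none higher (median −0.13; cpr-6 at −2.0, ges-1 at −1.38), and epidermis 3 of 23 higher and 4 lower (median 0.11; grd-3 at 1.91, wrt-4 at −2.84). In all, 11 list medians lay above and 5 below the random range.

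Heat shock was also set directly against bio-electrospray. The pals median was 2.41, with 14 of the 18 genes above the filter at least 2-fold higher, and the small heat shock protein median was 0.58, with 5 of 11 higher. Germline (−1.31), sperm (−1.18), cuticle collagen (−0.90), cell cycle (−0.65) and moulting (−0.35) medians were negative, and synaptic (0.82), FMRFamide-like neuropeptide (0.69), histone (0.55) and ion channel (0.40) medians positive. The calls outside the random range held in 9 of 10 alternatives for sperm (median up to −0.044) and for ion channels (median down to 0). UDP-glucuronosyltransferase genes were lower here, with a median of −0.16 (percentile 0.04), 8 of 45 members 2-fold lower and 2 higher. Of 11980 probe sets compared, 1027 were at least 2-fold higher and 870 lower on the heat shock array, 15.8% in all, and 9 list medians lay above and 6 below the random range.

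Some of the transcripts apart after bio-electrospray were apart in the same direction after heat shock. Among the 11368 probe sets above the filter in both comparisons with control, 12 were at least 2-fold higher in both. They measured clec-47 (2.26 after bio-electrospray and 2.87 after heat shock), Y58A7A.5 (2.60 and 2.5), Y58A7A.3, C49G7.10, acdh-1, swt-6, rcd-1, clc-19, fbxc-58, F53B2.8, gem-4, and F10G8.1 with C55B7.3 on 1 probe set. The 3 lower in both measured clec-258, fat-7 and argk-1 (−1.31 and −3.29). The probe set shared by dod-21 and cld-1 was lower after bio-electrospray (−1.69) and higher after heat shock (4.31), and T05E12.6 was the reverse (1.13 and −1.55). In contrast, acdh-2 (−0.07) and ugt-29 (0.10) lay near the control level after heat shock.

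Both sets of differences share the single control array, so an overlap arises without any effect. Simulated arrays that differed by noise only gave 5 probe sets higher in both and 5.82 lower in both, and independent lists would share 1.81 and 0.41. The correlation of the differences across probe sets was 0.20 (Spearman 0.16), against 0.50 (0.47 to 0.54) with noise only. Their covariance was 0.029 against a simulated 0.016. The noise of every simulated array was drawn from the bio-electrospray minus control differences, so it holds any effect of the spraying. Such equal noise sets the simulated correlation near 0.50. The observed differences had standard deviations of 0.18 (bio-electrospray) and 0.87 (heat shock), so the correlations cannot be compared. The simulated 5.82 lower in both exceeds the 5 probe sets lower after bio-electrospray, so that count is no firm reference. The simulated 5 higher in both came from the same noise, made equal in both directions. After bio-electrospray 26 of these probe sets were higher and 5 lower, so this count is no firm reference either. The control array could not be split, and part of the excess over independent lists may come from it.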

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

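Probe sets without a gene name take no part in the lists or the named genes. Of 895 such probe sets, 218 passed the filter for heat shock against control, and 18 of these were at least 2-fold higher on the heat shock array than on the control array, which put them here as a signal outside the named genes. A further 10 were at least 2-fold lower. The highest of them stood at 6.45 against 3.84, a difference of 2.61. After bio-electrospray 0 of 211 were 2-fold higher and 0 lower.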

How the results depend on the processing

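The alternatives were fixed before the data were examined. Counts of probe sets 2-fold apart stayed within 1.5 times the reported ones under quantile normalization and median and loess centring; the level filter itself removed no probe set 2-fold apart. They did not under the settings that follow, and the cause lies in their construction (differences of dim probe sets shrunk, fewer probe sets, another threshold). With an offset of 16, counts higher and lower were 12 and 1 for bio-electrospray against control, 516 and 519 for heat shock against control, 479 and 487 for heat shock against bio-electrospray, and 6 and 1 in both against control. Without shared probe sets the counts were 15 and 3, 680 and 509, 679 and 471, and 7 higher in both. At a threshold of 1.5-fold they were 84 and 69, 2087 and 1689, 2175 and 1592, and 37 and 53, and at 3-fold 8 and 2, 408 and 455, 389 and 419, and 3 and 1. Above the 75th percentile, 1 probe set was lower after bio-electrospray and 1 lower in both, and above the median in both arrays 3 and 1. Of probe sets apart after bio-electrospray 84.4% were higher, and 95.2% above the 75th percentile; for heat shock the share was 52.9%, and 49.05% after loess centring. In the skr and cul list the median turned to −0.023 without a level filter against control and −0.024 against bio-electrospray, and the cause was not tested. Of the other list medians 1202 stayed near the main value and 55 moved. Near meant inside the list's own 95% interval over genes, or within 1.5-fold for lists too small for one. Some intervals were wide, such as 0 to 6.20 for small heat shock proteins after heat shock, so this rule is a loose one. Of values for named genes 775 stayed within 1.5-fold and 25 moved. The sperm list ranged from −2.59 to −0.038 after heat shock, the pals list from 1.06 to 2.86, the germline list from −1.39 to −0.67 and the collagen list from −1.3 to −0.40. Levels near the floor limit every fold of a dim probe set.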

Other observations

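The gene families described first, and the tests of RNA degradation, of timing genes above the filter, of a whole-array shift, of the control array alone and of single probe sets of the acdh and hphd genes, were chosen after the results were seen. Among 64 families of gene symbols with at least 10 members outside the lists, 13 had a median difference between heat shock and control above the middle 95% of random lists and 8 below it. Claudin-like clc genes were highest, with 10 of 13 at least 2-fold higher and a median of 1.15, led by clc-11 (3.86) and clc-1 (1.54). Of the higher ones clc-11, clc-32, clc-25 and clc-23 lay below the median of the control array, at 2.44, 2.38, 2.74 and 2.55. The alternative settings were not run for the families. Neuropeptide-like nlp genes had 15 of 37 higher and 1 lower (median 0.72), with nlp-7 at 2.60, nlp-17 at 2.12 and nlp-26 at −2.0. The nssp genes had 4 of 25 higher (median 0.63; nssp-64 at 1.88), bestrophin genes 3 of 14 higher and 1 lower (median 0.60; best-13 at 1.57), and F-box fbxa genes 18 of 58 higher and 1 lower (median 0.59).

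On the lower side stood the hedgehog-related ground-like grl genes, with 6 of 11 at least 2-fold lower after heat shock (median −1.22; grl-16 at −2.78, grl-21 at −2.59). Astacin metalloprotease nas genes outside the moulting list had 7 of 14 lower and 1 higher (median −1.22; nas-27 at −2.56, nas-8 at −2.0). The dbd and idpp families had 7 of 12 and 6 of 12 lower (medians −1.09 and −1.07), with dbd-20 at −3.61 and idpp-9 at −3.66. In the idpp family 1 member was higher, idpp-16 at 2.18. Mitochondrial ribosomal protein genes had medians of −0.34 (mrps, 2 of 24 lower) and −0.20 (mrpl, 1 of 33 lower), opposite to the cytosolic ones. After bio-electrospray none of the named families had a member 2-fold apart except clc, with 1.

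Many more probe sets were 2-fold apart after heat shock than after bio-electrospray. After loess centring on level the count was still 60.7 times as large. The centring hardly changed the counts: 1969 became 1943 for heat shock, and bio-electrospray had 32 before and after. GCRMA as usually run already normalizes by quantiles, which leaves loess little to remove, so this decides little about a distortion that depends on brightness. Such a distortion may be a part of the cause: spike-in differences between heat shock and control ran from −1.07 (control level 5.51) to −0.15 (11.38). Of the 18 spike-in probe sets 2 were 2-fold apart there, against 0 between bio-electrospray and control. Second probe sets of the same genes went the same way in 96.5% of cases and were also 2-fold apart in 57.6%. The shared direction argues against noise of single probe sets as the whole cause. The mean 5′ minus 3′ level of 4 control transcripts was higher by 0.43 on the heat shock array, where degraded RNA would lower it. It rose most for catalase (0.78) and Gapdh (0.69), and by 0.14 for actin and 0.11 for ubiquitin. The catalase 5′ probe set stood at 3.03 on the control array, below the array median. These values speak only against more degradation in the heat shock sample, and the arrays may still differ in RNA quality. A difference between cultures, hybridizations or batches cannot be told apart from the treatment with 1 array per group, and the treatment itself may be the source.

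Germline, sperm, cell cycle, moulting and collagen lists were all lower after heat shock. The median of all genes lay 0.77 above the highest of these 5 list medians, but normalization between arrays holds that median near 0, so the value decides nothing about a shift of the whole array; against the bio-electrospray array the highest of them was −0.35, which argues against an unusual control array alone. Larvae held at 30 °C may have been less advanced in development: lin-28 and hbl-1, regulators of early larval stages, were higher by 1.52 and 2.0, and lin-29, a regulator of late stages, lower by −2.62. The pair chosen before this was seen, lin-14 and lin-28, left it open, since the lin-14 probe set lay at the floor on both arrays (−0.035). On the control array lin-29 stood at 6.09 and the sperm gene msp-36 at 6.24, so the untreated larvae may have been past the labelled L1 stage. Age at collection, a slower germline and a direct response to heat remain untested alternatives.

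After bio-electrospray acdh-1, acdh-2 and hphd-1, which act in or near propionate breakdown, were higher together. Other probe sets of acdh-2 and hphd-1 were higher by at least 0.76, which argues against noise of single probe sets for those genes. For acdh-1, which has 0 other probe sets, such noise stays open. With an offset of 16 the smallest of the 3 differences, over the brightest probe set of each gene, was 0.97. The other hphd-1 probe set was then higher by 0.55. These values argue against the floor as the whole cause. The brightest probe sets of acdh-1 and hphd-1 lay far above the floor, so the offset could hardly move them. The offset took acdh-2 from 8.85-fold to 3.91-fold, so the size of its difference depends on the floor. The other genes of the pathway, hach-1 (0.94), ech-6 (0.64) and alh-8 (0.30), had a median of 0.64, so a raised propionate pathway is a candidate explanation. After heat shock the same genes went both ways, with acdh-1 at 1.11, alh-8 at 0.81, ech-6 at 0.28, hach-1 at −0.54 and hphd-1 at −0.81. Diet, including the vitamin B12 supply, and culture conditions were not tested and stay open with 1 array.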
